A study of Homo sapiens with 4 samples.

How the data were processed

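RNA from 4 libraries of HFL1 cells, 2 labelled WT and 2 labelled KO, was sequenced on an Illumina NovaSeq 6000 and aligned as paired-end reads, per the labels' protocols. Per the submitters' processing notes the aligner was HISAT2 2.0.5, and the notes name the builds hg38 and mm10. Gene identifiers and coordinates of all 58735 genes in the table equalled those of GENCODE release 29 on GRCh38, so coordinates are given on that build. The values analysed were the FPKM values the authors deposited, 1 per gene and library. The counting tool, the annotation and any scaling between libraries are not given in the sources used here. FPKM multiplied by gene length was a whole multiple of a single step in each library for 100% of values (tolerance 0.01), so reads were recovered: 17715774, 16173899, 17699349 and 16622382 for WT replicates 1 and 2 and KO replicates 1 and 2. The divisor implied by those steps was 1.03, 1.01, 0.990 and 0.986 times the recovered reads, and the median-of-ratios factor of the deposited values was 1.0046 in every library, so the values already carried a scaling of that kind. The mitochondrial share of reads was 9.66%, 12.7%, 9.34% and 9.71%. The FPKM unit has no depth of its own, and floors were set at 3 reads per library.

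Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 14100 in all, with an intensity-dependent prior (prior df 3.54, residual df 2) and no replicate block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Unless stated otherwise, log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and folds are ratios of mean FPKM. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333. Gene lists numbered 40, fixed before the data were examined, and 36 had at least 5 measured members and entered the camera test with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over those 36. They cover genes that rise or fall in senescence, the secretory phenotype, p53, NF-kB, interferon, WNT, BMP, YAP, TGF-beta and NRF2 targets, mitosis, DNA replication, matrix, contraction, stress and metabolic groups, fibroblast and lung mesenchyme genes, and markers of other cell types. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in a single direction, were the alternatives. Fry's adjusted p under 0.05 held for all called lists except matrix proteases, nuclear oxidative phosphorylation and fibroblast genes, and also for the matrix, BMP, WNT, calumenin family, intermediate filament and epithelial lists, which camera did not call. The calumenin family list includes CALU, the targeted gene, so its result does not describe the other members alone.

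Named genes were CALU, the 12 protein-coding genes with the largest positive and the 12 with the largest negative log2 change past the threshold with a mean of at least 5 FPKM in the higher group and both KO libraries on the same side of both WT libraries, up to 4 measured members of each list (those past the threshold by size, or the most abundant where fewer than 2 passed), and VIM, CDKN1A, CDKN2A, LMNB1, COL1A1 and ACTA2. Some genes that this rule picks are not reported here. Genes named outside this rule are said to be chosen after their values were seen. Genes whose annotation overlaps another gene, such as CALU with a small pseudogene and KRT8 with KRT18, or that share sequence with a copy, are uncertain where counting could split reads.

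The fit was tested on simulated data with 2 libraries per group, 13925 genes tested and a dispersion of 0.0218. Of 40 genes changed at each fold, 39 were recovered at 4-fold, 25 at 0.25-fold, 17 at 2-fold, 11 at 0.5-fold and 1 at 1.5-fold. Recovery pooled over the 4-fold and 0.25-fold changes fell short of the pass mark first set for this test, with the misses mostly at 0.25-fold. The mark was lowered after that result, with the fit left as it was. Of 112 calls, 19 were false, a share of 17% at an adjusted p under 0.05, and all 19 lay outside protein-coding genes. All simulated genes shared the same dispersion and had no difference by replicate number. These shares therefore need not hold for the measured libraries. With no gene changed, 6 genes and 0 lists were called. A 2-fold rise of the mitosis list alone gave a camera adjusted p of 2.94e-55 with the preset correlation. With an estimated correlation the camera adjusted p was 0.111, so that setting missed a known change in the simulated data. The simulated genes varied independently, whereas the estimated correlation of the measured mitosis list was 0.793. The simulation therefore cannot tell which correlation suits the measured lists. The settings also differ in more than the correlation. For the p53 and secretory phenotype lists the estimated correlation, -0.0311 and -0.00728, lay below the preset 0.01. Their unadjusted camera p still rose from 3.18e-14 and 1.2e-10 to 0.0132 and 0.0196. A higher correlation between members thus cannot account for the rise in these lists. Alternatives covered the pseudocount (0.1 and 0.5), the filter, the normalization, the prior, the replicate block, weights on recovered reads by voom, and leaving out each library. Within each group the libraries differed by more than sampling noise (chi-square per degree of freedom 23.1 in WT and 34.4 in KO), so neither library was taken as a second deposit of the other, which does not show separate cultures.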

Results

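RNA sequencing was reported for HFL1 cells, a human fetal lung fibroblast line per the labels, in 4 libraries: 2 labelled WT and 2 labelled KO for calumenin. Calumenin, encoded by CALU, is a calcium-binding protein of the secretory pathway. The design asked how loss of calumenin affects senescence and fibrosis programmes. Whole reads recovered from the deposited FPKM values numbered 17715774 and 16173899 in the WT libraries and 17699349 and 16622382 in the KO libraries. A level of 3 reads corresponded to 0.0404 FPKM or less for CALU, and such floors cover counting error only. Log2 values correlated at 0.975 between the WT libraries, 0.967 between the KO libraries and 0.891 to 0.914 between groups, across genes, which are not independent replicates. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

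CALU was lower in both libraries labelled KO, at 6.59 and 5.95 FPKM against 87.7 and 81.8 FPKM in the libraries labelled WT. Its mean fell from 84.7 ± 4.15 to 6.27 ± 0.459 FPKM (SD, n = 2 per group), a 13.5-fold lower level, with a log2 change of -3.56 (SE 0.14, limma adjusted p = 0.00154). The gene (ENSG00000128595) lies on chromosome 7 from 128739292 to 128771807 on the plus strand of GRCh38. The KO libraries still held 966 CALU reads, and gene-level values do not show which exons these came from. Among the other members of its protein family, RCN1 stood at 37.9 ± 0.907 FPKM in WT and 28.6 ± 2.09 FPKM in KO (limma adjusted p = 0.0921), SDF4 at 36.0 and 30.8 FPKM, and RCN2 at 8.67 and 10.03 FPKM, none past the threshold, although RCN1 passed with GC content and length removed (adjusted p = 0.0173). Of the 5 measured family members including CALU, 0 rose and 1, CALU itself, fell, also 0 and 1 adjusted over the list alone. The list did not pass the list test (camera adjusted p = 0.378).

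**Figure D1:**
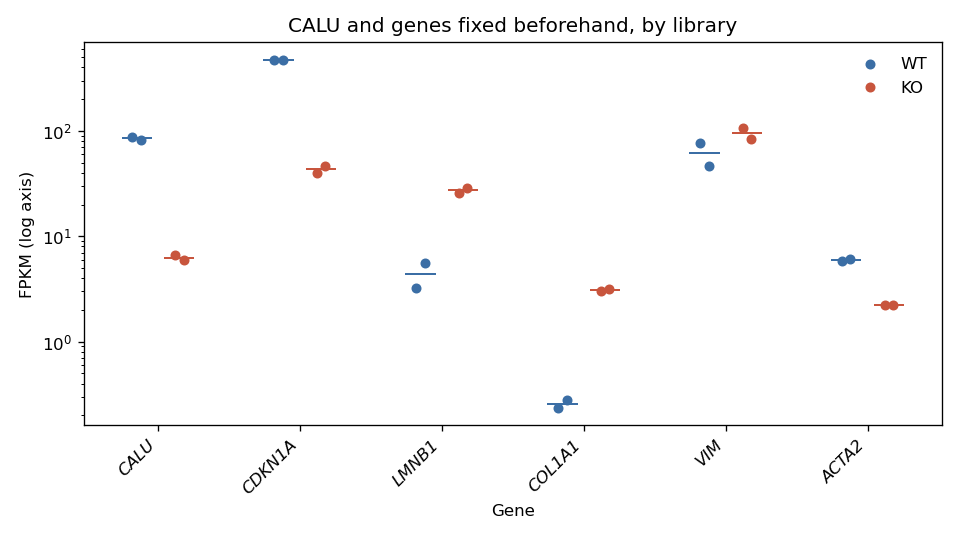
FPKM on a log axis for CALU and 5 genes fixed before the data were examined, with points for the 2 WT and 2 KO libraries and a short line at each group mean. CALU lies at 87.7 and 81.8 FPKM in WT and at 6.59 and 5.95 FPKM in KO, and LMNB1 and CDKN1A move in opposite directions.

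The labelled fibroblast libraries held few transcripts of several fibroblast genes. COL1A2, a chain of type I collagen, and POSTN, the matrix protein periostin, had 0 reads in all 4 libraries, which allows up to 0.0164 and 0.0335 FPKM. DCN and FAP had 1 read each in total, and COL3A1, PDGFRA and PDGFRB stayed at or below 0.235, 0.186 and 0.111 FPKM. The keratins of simple epithelia were abundant, with KRT8 at 349 to 926 FPKM and KRT18 at 326 to 741 FPKM across libraries. Of 13 fixed fibroblast genes, 7 stayed below 1 FPKM in every library, and the median of the highest levels of the 13 was 0.811 FPKM. Others were measured in every library, with S100A4 at 449 to 1352 FPKM, NT5E at 13.6 to 39.6 FPKM and TWIST2 at 6.60 to 11.6 FPKM. Genes of other lineages were mostly low too: 7 of 12 epithelial, 9 of 10 endothelial, 9 of 10 leukocyte, 3 of 6 mesothelial markers and 6 of 9 entries for mural markers stayed below 1 FPKM in every library. Of 38 fixed collagen and matrix genes, 15 stayed below 1 FPKM in every library, 3 of these at 0. Others were measured, such as FN1 at 28.9 to 126 FPKM and COL5A1 at 7.75 to 35.2 FPKM across libraries. All genes named in this paragraph belong to fixed lists, but only FN1, COL5A1, KRT8, NT5E and TWIST2 were picked by the naming rule. The rest were chosen after their values were seen.

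**Figure D2:**
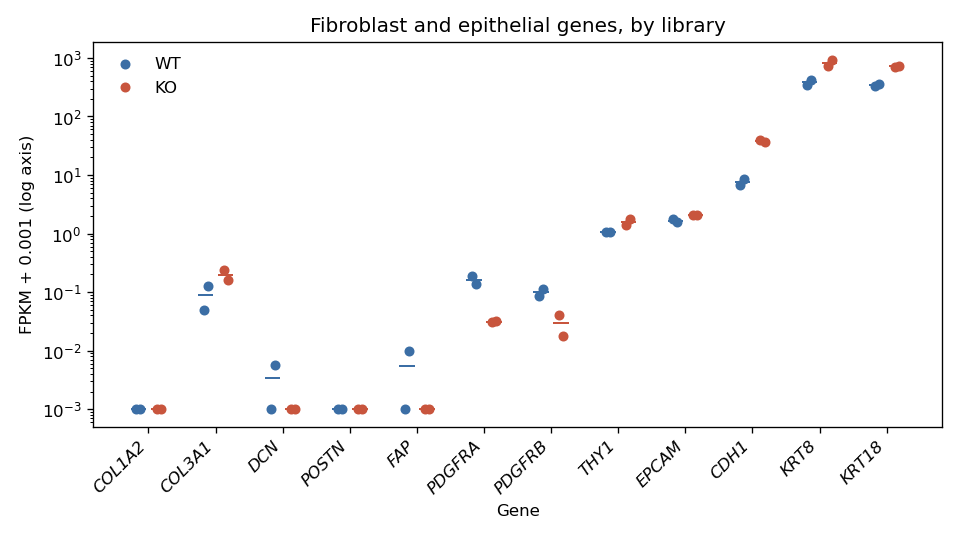
FPKM plus 0.001 on a log axis for 8 fibroblast genes and 4 epithelial genes, with points for the 2 WT and 2 KO libraries and a short line at each group mean. COL1A2 and POSTN lie at 0 reads in every library, while KRT8 reaches 349 to 926 FPKM. Apart from KRT8 and CDH1, the genes shown were chosen after their values were seen. Fibroblast genes measured at higher levels, such as S100A4, NT5E and TWIST2, are not shown. Of 12 fixed epithelial markers, 7 stayed below 1 FPKM in every library, and these are not shown either.

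Of 14100 genes tested, 1711 rose and 1572 fell in KO, and 10817 did not pass the threshold (limma, Benjamini-Hochberg adjusted p under 0.05). Of 11504 protein-coding genes tested, 1481 rose and 1278 fell. Of the 14100 genes tested, called changes of at least 1 in size on the log2(FPKM + 1) scale numbered 673 upward and 639 downward. These counts leave out some low genes whose mean FPKM changed at least 2-fold. Among protein-coding genes picked by size, CLDN2, which forms paracellular cation pores, rose 47.0-fold from 0.696 ± 0.0529 to 32.8 ± 5.54 FPKM (SD, n = 2 per group, log2 4.31, SE 0.16). BAAT, which conjugates bile acids, rose 73.1-fold from 0.184 ± 0.122 to 13.4 ± 1.73 FPKM (138-fold without WT replicate 2), and TM4SF4 rose 23.3-fold to 49.4 ± 4.90 FPKM. CD24 rose 16.3-fold to 480 ± 47.1 FPKM, although it shares sequence with a pseudogene copy. The other 8 picked genes that rose were the cell-division genes DLGAP5, KIF20A, ASPM, MKI67, PLK1, HMMR, CDC20 and PTTG1, which rose 10.03-fold (CDC20) to 27.4-fold (KIF20A); without WT replicate 2 the folds were 47.8 for KIF20A, 37.2 for DLGAP5, 33.03 for HMMR and 19.2 for MKI67. LCN2, an iron-siderophore carrier, fell from 89.8 ± 16.1 to 4.22 ± 1.22 FPKM, 21.3-fold lower. ICAM1, an adhesion receptor for leukocytes, was 73.6-fold lower, and PRSS35 43.0-fold lower. SLC6A12 was 31.8-fold lower and RAB17 26.1-fold lower. SLCO4A1 was 12.7-fold lower, CHAC1, which degrades glutathione, 13.4-fold and CXCL8, a neutrophil chemokine, 11.01-fold lower. CCL2, a monocyte chemokine, was 9.60-fold lower and CDKN1A 10.9-fold lower. With no filter on low values 183 genes were higher and 193 lower, and 76 named genes lost their call at adjusted p of 0.0501 to 0.156, among them MKI67, CDC20, LMNB1 and ACTA2. Without WT replicate 1 the counts were 505 higher and 537 lower, and without WT replicate 2 they were 677 and 614.

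Genes of cell division rose together in KO. All 28 measured mitosis genes rose, with a median log2 change of 2.54 (camera adjusted p = 1.91e-19 with the preset correlation, adjusted p = 0.543 with an estimated correlation). MKI67, a marker of cycling cells, rose from 3.21 ± 1.76 to 37.8 ± 5.93 FPKM (SD, n = 2 per group, log2 3.26, SE 0.31). DLGAP5, a spindle protein, rose from 1.12 ± 0.630 to 25.0 ± 2.50 FPKM, and PLK1, a mitotic kinase, from 1.40 ± 0.561 to 21.6 ± 0.860 FPKM. Of 27 measured DNA replication genes, 25 rose and 0 fell (camera adjusted p = 6.65e-13, adjusted p = 0.543 with an estimated correlation), including UHRF1 at 4.39-fold, RRM1, a subunit of ribonucleotide reductase, at 3.74-fold, GINS1 at 3.91-fold and CDC45 at 4.32-fold (6.71-fold without WT replicate 2). Adjusted over the list alone, 28 mitosis and 25 replication genes rose. All 8 measured genes known to decline in senescent cells rose (camera adjusted p = 7.93e-06, adjusted p = 0.406 with an estimated correlation), also 8 adjusted over the list alone. LMNB1, a nuclear lamin, rose 6.19-fold from 4.39 ± 1.60 to 27.2 ± 2.35 FPKM, HMGB2 6.21-fold, HMGB1 2.997-fold and EZH2 2.87-fold. The epithelial adhesion gene CDH1 rose 5.01-fold, from 7.67 ± 1.24 to 38.4 ± 2.07 FPKM, in the same libraries.

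Of 30 measured p53 target genes, 25 fell and 0 rose, 26 and 0 adjusted over the list alone, with a median log2 change of -1.14 (camera adjusted p = 3.82e-13, adjusted p = 0.236 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 470 ± 2.64 to 43.3 ± 4.91 FPKM (SD, n = 2 per group, log2 -3.42, SE 0.16). GDF15, a stress-induced cytokine, was 8.16-fold lower, SESN2 4.39-fold and MDM2, the ubiquitin ligase of p53, 3.84-fold lower. Of 11 measured genes known to rise in senescence, 5 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.543 with an estimated correlation). IGFBP5 was 12.2-fold lower, from 18.3 ± 10.9 to 1.51 ± 0.000258 FPKM (7.05-fold without WT replicate 2), while IGFBP3 rose 2.002-fold. The call of this list was lost without KO replicate 1 (adjusted p = 0.0544) and with GC content and length removed (adjusted p = 0.0554), and that of IGFBP3 without either WT replicate (adjusted p = 0.0614 and 0.102). CDKN2A and CDKN2B had 0 reads in all 4 libraries, which allows up to 0.0423 and 0.0451 FPKM if reads shared with AL359922.1, an overlapping annotation with 0 reads, were counted.

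Of 34 listed genes of the senescence-associated secretory phenotype, 14 stayed below 1 FPKM in every library. Among them was IL6, chosen after its values were seen, with 32 reads in total. Of the 20 measured, 15 fell and 0 rose, 16 and 0 adjusted over the list alone, with a median log2 change of -1.33 (camera adjusted p = 8.66e-10, adjusted p = 0.236 with an estimated correlation). CSF2, a myeloid growth factor, stood at 6.001 ± 0.374 FPKM in WT and at 0 reads in KO, at least 26.6-fold lower against a floor of 3 reads per library. Of 20 measured NF-kB target genes, 17 fell and 0 rose, the same numbers adjusted over the list alone, with a median log2 change of -1.74 (camera adjusted p = 1.76e-13, adjusted p = 0.236 with an estimated correlation). CXCL8 fell from 70.9 ± 19.7 to 6.44 ± 1.79 FPKM, CCL2 from 183 ± 0.144 to 19.0 ± 1.85 FPKM, and CXCL1 from 156 ± 7.69 to 27.8 ± 7.10 FPKM. Several of these chemokine genes and ICAM1 belong to both lists, so the lists are not independent of each other. The same holds for the p53 and senescence lists, which share CDKN1A and GDF15, and for the p53 and integrated stress lists, which share SESN2. Of 24 measured genes of the integrated stress response, 18 fell and 0 rose, 19 and 0 adjusted over the list alone (camera adjusted p = 9.06e-10, adjusted p = 0.543 with an estimated correlation). CHAC1 fell from 29.6 ± 5.92 to 2.21 ± 0.185 FPKM, STC2 was 7.06-fold lower and PSAT1, an enzyme of serine synthesis, 3.46-fold lower. Of 17 measured immediate early genes, 12 fell and 1 rose, 13 and 1 adjusted over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.543 with an estimated correlation). EGR1 was 23.6-fold lower, KLF4 7.52-fold, FOSL1 7.30-fold and IER3 4.35-fold lower.

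**Figure D3:**
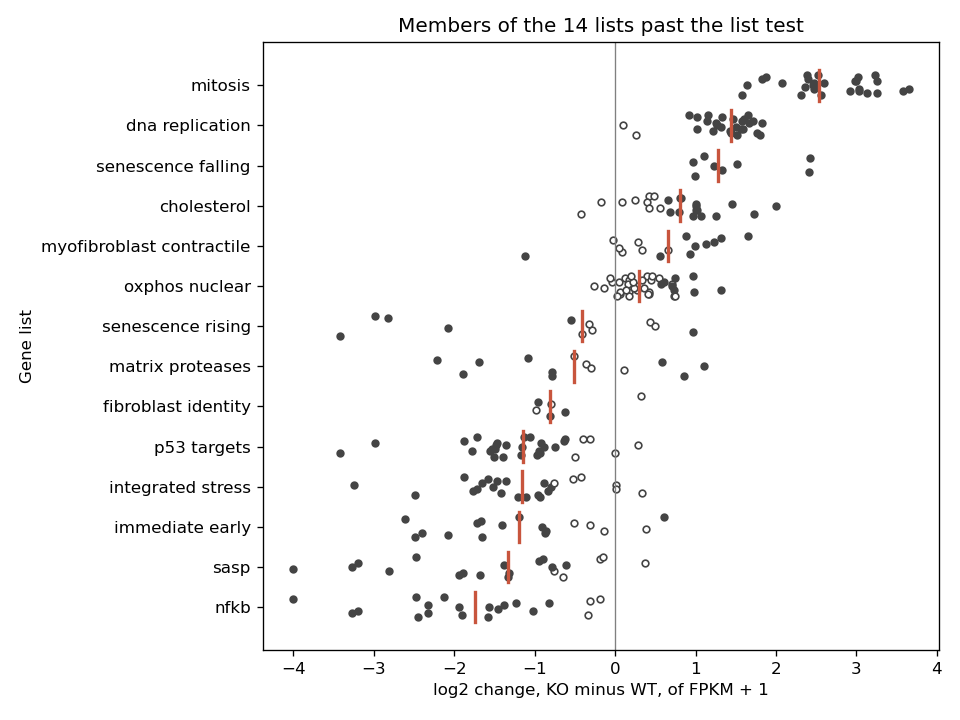
Log2 change of FPKM plus 1, KO minus WT, for each measured member of the 14 lists past the list test, with filled points for genes past adjusted p 0.05, open points for the others and a red bar at each list's median. Every mitosis gene lies to the right of 0, around a median of 2.54, and the NF-kB list has its median at -1.74.

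Matrix and contractile genes moved both ways. Of 22 measured collagen and matrix genes, 8 rose and 5 fell, 9 and 6 adjusted over the list alone, and the list did not pass the test (camera adjusted p = 0.695), with a median log2 change of -0.05 and a mean of 0.21, so median and mean differed in sign. VCAN, the proteoglycan versican, rose 8.47-fold, from 1.65 ± 0.208 to 13.96 ± 2.999 FPKM (SD, n = 2 per group), FN1, fibronectin, 3.74-fold from 31.8 ± 4.09 to 119 ± 10.8 FPKM, and COL5A1 3.98-fold. COL1A1 rose 12.1-fold from a low level, 0.257 ± 0.0320 to 3.10 ± 0.0823 FPKM (log2 1.71, SE 0.15). Of 15 measured contractile genes, 8 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00189, adjusted p = 0.543 with an estimated correlation). CNN2 rose 3.35-fold, MYLK, the myosin light chain kinase, 3.06-fold and TPM1 2.42-fold, ITGA11 rose 14.02-fold to 1.41 FPKM (23.3-fold without WT replicate 2), and the member that fell was ACTA2, smooth muscle actin, from 5.98 ± 0.153 to 2.21 ± 0.00602 FPKM. Of 13 measured matrix proteases and inhibitors, 6 fell and 3 rose, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0459, adjusted p = 0.642 with an estimated correlation). PLAU, the urokinase, was 4.80-fold lower, PLAT 5.57-fold and TIMP4 3.39-fold lower, while MMP24 rose 2.20-fold. The protease list lost its call with a pseudocount of 0.1, with quantile normalization, with scaling by total reads, without WT replicate 1, without KO replicate 2, without chromosomes 4, 17 and X, and with GC content and length removed (adjusted p = 0.0531 to 0.105). MMP24 lost its call without WT replicate 1 (adjusted p = 0.0925) and ITGA11 without KO replicate 1 (adjusted p = 0.052).

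VIM, which encodes vimentin, stood at 61.6 ± 21.004 FPKM in WT and 95.5 ± 15.4 FPKM in KO (SD, n = 2 per group, log2 0.66, SE 0.27, limma adjusted p = 0.136), a difference that did not pass the test. With a replicate block, and under no other alternative, VIM passed (limma adjusted p = 0.0112). Of 13 measured intermediate filament and linker genes, 5 rose and 2 fell, 5 and 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.442). KRT8 rose 2.14-fold, KRT19 2.93-fold and LMNB1 6.19-fold, while MACF1, a cytoskeletal linker, was 2.76-fold lower. KRT8 overlaps KRT18 in the annotation. Of 6 measured fibroblast genes, 3 fell, 5 adjusted over the list alone (camera adjusted p = 0.0474, adjusted p = 0.642 with an estimated correlation), namely NT5E, 2.02-fold lower, ENG, 3.09-fold, and TWIST2, 1.62-fold lower. Of 5 measured epithelial markers, CDH1 rose and CLDN4 and KRT15 fell, 5.12-fold and 24.7-fold lower, the same 1 and 2 adjusted over the list alone (camera adjusted p = 0.485). The fibroblast list lost its call with a pseudocount of 0.1 or 0.5, with scaling by total reads, without KO replicate 1, and with GC content and length removed (adjusted p = 0.0552 to 0.0928). Without WT replicate 1 the calls of KRT8, NT5E, ENG and TWIST2 were lost (adjusted p = 0.0939 to 0.219), and each was lost without at least 1 other library too.

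Genes of cholesterol synthesis and uptake rose. Of 24 measured members, 15 rose and 0 fell, 20 and 1 adjusted over the list alone (camera adjusted p = 8.77e-07, adjusted p = 0.543 with an estimated correlation). HMGCS1, an enzyme of the mevalonate pathway, rose 3.69-fold from 6.03 ± 0.788 to 22.3 ± 1.54 FPKM (SD, n = 2 per group), EBP 2.86-fold and INSIG1 2.50-fold. Of 40 nuclear genes of oxidative phosphorylation, 9 rose and 0 fell, also 9 and 0 adjusted over the list alone, with a median log2 change of 0.30 (camera adjusted p = 0.00189, adjusted p = 0.642 with an estimated correlation). UQCRFS1 rose 2.004-fold, ATP5MC1 2.04-fold, COX8A 2.62-fold and NDUFS7 2.22-fold. Without WT replicate 1 this list and these 4 genes lost their calls (adjusted p = 0.0559 for the list and 0.0773 to 0.143 for the genes), and the list lost it without KO replicate 2 as well (adjusted p = 0.153).

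Endoplasmic reticulum chaperones and TGF-beta targets did not pass the list test. Of 27 measured chaperone and folding genes, 4 fell and 3 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.47). HSPA5, the chaperone BiP, fell from 289 ± 35.1 to 160 ± 6.60 FPKM (SD, n = 2 per group), DNAJB9 was 2.96-fold and HERPUD1 2.13-fold lower, and CALR, calreticulin, stood 1.80-fold higher at the edge of the threshold (adjusted p = 0.0488). Without any 1 library CALR and HSPA5 lost their calls (adjusted p = 0.0599 to 0.269 and 0.0632 to 0.185), as did HERPUD1 without WT replicate 1 (adjusted p = 0.0696), and CALR lost it also with a pseudocount of 0.1 (adjusted p = 0.0508), cyclic loess (adjusted p = 0.0525) and scaling by total reads (adjusted p = 0.0516). Of 16 measured TGF-beta targets, 5 fell and 2 rose, 6 and 3 adjusted over the list alone (camera adjusted p = 0.22). CTGF was 3.23-fold and LTBP2 2.56-fold lower, while TGFBI rose 2.61-fold, from 85.8 ± 0.152 to 224 ± 18.7 FPKM.

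The remaining lists did not pass the list test. WNT targets included DKK1, which rose 4.02-fold, and AXIN2 (3 rose and 2 fell of 8, 4 and 2 adjusted over the list alone, camera adjusted p = 0.223), and BMP targets included BAMBI and ID1, which fell (1 and 4 of 9, 1 and 5 adjusted over the list alone, camera adjusted p = 0.196). YAP targets held 4 that rose and 5 that fell of 21, the same adjusted over the list alone (camera adjusted p = 0.424), hypoxia and glycolysis genes 6 and 4 of 25, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.827), and interferon genes 3 and 2 of 20, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.528). Collagen-processing enzymes held 2 that rose and 2 that fell of 21, the same adjusted over the list alone (camera adjusted p = 0.972), with LOXL4 and LOXL2 lower. Calcium-handling genes held 4 and 3 of 16, the same adjusted over the list alone (camera adjusted p = 0.47), and NRF2 targets 3 and 2 of 24, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.424). Autophagy and lysosome genes held 0 and 3 of 30, the same adjusted over the list alone (camera adjusted p = 0.241), among them SQSTM1, the selective autophagy receptor, which fell by 1.77 on the log2 scale. Cytosolic heat shock genes held 3 and 0 of 16, the same adjusted over the list alone (camera adjusted p = 0.195), with HSPB1 among the 3. Of 31 proteasome genes PSMD6 alone rose, 0 adjusted over the list alone (camera adjusted p = 0.498), and of 53 ribosomal protein genes RPL3 and RPL22 rose, 0 adjusted over the list alone (camera adjusted p = 0.241). The 13 mitochondrially encoded genes held 0 of either direction, also 0 adjusted over the list alone (camera adjusted p = 0.238), with MT-CO1 at 16846 and 20437 FPKM in WT. Vitamin K genes held 0 and 1 of 8, the same adjusted over the list alone (camera adjusted p = 0.972), with PRRG4 lower, a median of 0.12 and a mean of -0.08. Polyadenylated histone genes held 1 and 1 of 8, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.827), a median of 0.0044 and a mean of -0.04. Lung mesenchyme genes held 3 and 1 of 8, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.471), and TBX4 was the member that fell. Too few members were measured to test the endothelial (0), leukocyte (1), mesothelial (3) and mural (2) lists, and CD14 and CALB2 fell, by 1.42 and 3.03 on the log2 scale. Without WT replicate 1 the calls of ID1, LOXL2, HSPB1, PSMD6, RPL3, RPL22 and TBX4 were lost (adjusted p = 0.0508 to 0.311), and those of RPL3 and RPL22 were lost without any 1 library.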

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

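Removing GC content and length, scaling by total recovered reads, and leaving out chromosomes 4, 17 and X were added after seeing the data. The CALU log2 change kept its direction and call under every alternative run. With no filter on low values 183 genes were higher and 193 lower, all of them among those of the main analysis, with 32306 genes tested. With an FPKM of at least 5 in 2 libraries, 1259 genes were higher and 1041 lower. Of the 14100 genes tested, called changes of at least 1 in size on the log2(FPKM + 1) scale numbered 673 upward and 639 downward. Without 1 library, which leaves a lone sample assumed to vary like the other group, 505 to 1321 were higher and 537 to 1260 lower, the lowest without WT replicate 1. The libraries share replicate numbers, and number 2 minus number 1 deviations correlated across genes at 0.411 between groups. By number, 167 genes differed at an adjusted p under 0.05. Libraries of the same number thus share some difference, but there are 2 pairs and the labels do not say what it is. With the replicate block 2968 genes were higher and 2577 lower, including all 1711 and 1572, and VIM (adjusted p = 0.0112), RCN1 (adjusted p = 0.037) and VKORC1L1 (adjusted p = 0.0351) passed the threshold. With GC content and length removed RCN1 and VKORC1L1 passed (adjusted p = 0.0173 and 0.0449). With an estimated correlation 0 lists were higher and 0 lower, so all 14 called lists lost their call, with fry the matrix protease, fibroblast and oxidative phosphorylation lists lost it, and with GC content and length removed 5 lists were lower. Higher genes made up 47.0% to 54.7% of calls over all settings, against 52.1%. Changes of sign occurred only for genes that were not called, and the cause was not tested. Leaving out each library in turn gave log2 changes of -0.1003 to 0.039 for PSMC4, -0.549 to 0.121 for PSMB5, -0.260 to 0.0186 for MT-CO1, -0.0843 to 0.613 for MT-CO3, -0.109 to 0.334 for MT-ATP6 and -0.0705 to 0.0216 for NOTCH3. MT-ATP6 stood at 0 with quantile normalization and NOTCH3 at 0.109 with GC content and length removed. The counts for genes that follow leave out CALU, which is among the 148 named genes. Of the other comparisons of the named genes with an alternative, 2538 kept direction and call, 204 lost the call and 5 gained it. Of comparisons of called lists with a preset-correlation alternative, 249 kept the call. Another 16 lost it, all of the matrix protease, fibroblast, senescence and oxidative phosphorylation lists. The median-of-ratios scaling moved nothing, since its factor was the same in all libraries.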

Other observations

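The tests of transcription factor families, replicate number, fibroblast genes, carcinoma line genes, mitosis genes and copy number were chosen after the results were seen, while those of GC content, length and replicate spread for chromosomes 17 and X were set before theirs. By the families of the deposited annotation, the bZIP family fell (camera adjusted p = 0.00088, adjusted p = 0.769 with an estimated correlation), with 14 of 35 measured members lower and 2 higher. FOSL1 was 7.30-fold lower, ATF3 6.66-fold, JUN 3.30-fold, DDIT3 3.86-fold and NFE2L1 2.73-fold lower, while ATF6B rose 1.75-fold. The annotated family that holds the NF-kB and NFAT factors had 3 of 7 lower and 0 higher (camera adjusted p = 0.0262, adjusted p = 0.769 with an estimated correlation), namely RELB, from 21.03 ± 2.65 to 3.38 ± 0.0494 FPKM, NFKB2, 2.89-fold lower, and RELA, 1.53-fold lower, and no NFAT member passed the threshold. The ZBTB family had 10 of 36 lower and 0 higher (camera adjusted p = 0.00623, adjusted p = 0.769 with an estimated correlation), with BCL6, a transcriptional repressor, 3.54-fold lower. FOSL1, JUN and ATF3 are also in the immediate early list, ATF3 and DDIT3 in the integrated stress list, and RELB and NFKB2 in the NF-kB list. The results of those families are therefore not independent of these lists.

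By replicate number, 167 genes differed in the same way in both groups, number 2 against number 1. MT-ATP8 stood at 83.6 and 47.4 FPKM in the libraries numbered 1 and at 1080 and 946 FPKM in those numbered 2, and RN7SL2 at 56.4, 22.8, 499 and 356 FPKM in the same order.

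Of the 13 fixed fibroblast genes, 7 stayed below 1 FPKM in all 4 libraries and S100A4, NT5E and TWIST2 were measured in each, while the matrix genes COL1A2 and POSTN had 0 reads. A minority of other cells would leave abundant fibroblast transcripts, but the 13 had a median highest level of 0.811 FPKM, and depth is argued against as well, since 3 reads gave at most 0.179 FPKM for these genes. As a hypothesis, the cells may belong to an epithelial carcinoma line of the A549 type, which stays open: 16 genes known to be abundant there had a median of 113 FPKM in WT, with GPX2 at 296, NQO1 at 289 and AKR1C2 at 316 FPKM, but they were listed after values of some of them were seen, so this does not decide it. Against it, 5 of the 16 stayed below 10 FPKM in both groups, such as CPS1 at 0.706 and CES1 at 0.865 FPKM in WT. In addition, 4 of the 16 are also in the NRF2 list, and other lines could share this profile. On chromosome 9, CDKN2A and CDKN2B had 0 reads and MTAP 28, but all overlap AL359922.1, which had 0 as well, and reads shared with it may not have been counted, while KLHL9, IFNE and DMRTA1 on either side had 3269, 501 and 416.

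Mitosis genes were higher and CDKN1A lower in KO. Exchanged group labels are argued against by CALU, 13.5-fold higher in the libraries labelled WT. Shifts of chromosomes 4, 17 and X are argued against too, since the 22 mitosis genes elsewhere had a median log2 change of 2.54. Loss of calumenin and a difference in clone, density or passage between the cultures may each account for it and were not tested, since the labels name no culture apart from the group.

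Chromosomes 17 and X differed between KO and WT. Their median log2 changes were -0.21 over 654 genes and 0.37 over 329 genes, against 0.05 for all genes. These are log2 ratios of mean FPKM + 0.1, over genes with a mean of at least 3 FPKM. Both had a permutation adjusted p of 0.0012, from the smallest p that 10000 draws can give, 1e-04. Chromosomes 4 and 20 also passed (permutation adjusted p = 0.0023 and 0.017). In overlapping windows of 60 genes, 34 of 60 on chromosome 17 lay below the random range of -0.22 to 0.31, and 22 of 27 on chromosome X above it. Such windows share genes and are not separate findings. The draws treat neighbouring genes as independent and do not measure the spread between cultures. With GC content and length removed the medians of chromosomes 17 and X were -0.19 and 0.29, outside the random ranges of the corrected values. A trend with GC content or length is thus not the whole source. The corrected medians are on the log2(FPKM + 1) scale, so their sizes cannot be set against those before. Chromosome 4, at 0.19 before, lay at 0.09 inside its range, but these values differ in scale as well as in the correction. Chromosomes 19 and 20, at 0.14 and -0.09 with GC content and length removed, lay outside their ranges. Replicate libraries shifted chromosomes 17 and X by at most 0.402 times their shift between KO and WT, while chromosome 19 shifted by 0.26 between the KO replicates. A different copy number in the cultures cannot be told apart from a shift in gene regulation: the medians of 4 parts of like gene number ran from -0.35 to -0.10 on chromosome 17 and from 0.29 to 0.56 on chromosome X, all on the side of the shift, but their ranges of 0.249 and 0.262 were wider than permuted positions gave (permutation p = 8e-04 and 0.04), as either genes regulated in groups or a copy change of a segment could give. Copy number itself was not measured.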
